A study of Mus musculus with 25 samples.

How the data were processed

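Gene expression was measured in the spleen of male BALB/c and CBA/Ca mice with one-colour NimbleGen oligonucleotide arrays, 50 arrays for 25 mice, 2 arrays per mouse. Mice received for 8 weeks a feed poor in methionine and without choline or folic acid, or were controls, per the labels. The control diet is not described in the labels used here. The labels give 7 BALB/c controls, 6 BALB/c mice on the diet, 6 CBA/Ca controls and 6 CBA/Ca mice on the diet. The tissue tag of 3 CBA/Ca diet mice reads kidney while their titles read spleen. The groups follow the titles. The series design text names kidney and liver of BALB/c, which is not what the sample labels say.

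The deposited scanner files hold 1 intensity per probe, and the mismatch column is 0 throughout. The submitters' processing notes name RMA, with no version given in the sources used here. Medians of the deposited intensity differed by at most 0.0111% between arrays of 1 slide and ranged from 491 to 988 between slides, so arrays had been brought to 1 distribution within slides and not between them. Whether background had been removed before deposit is not given in the sources used here. The deposited value table is on a log2 scale and equals the mean log2 intensity of the probes and arrays of a mouse. Its column medians ran from 9.07 to 9.91.

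Values were computed from the intensities with limma 3.58.1 in R 4.3.3. Background was corrected with normexp (offset 50), log2 values were quantile normalized over all 50 arrays, and the 135054 gene probes were summarised by median polish into 42575 sequence identifiers. Arrays of a mouse were averaged. Identifiers were tested separately. Symbols came from the RefSeq table of assembly GRCm38.p6, by accession and then by Entrez number: 38643 identifiers were named (21703 genes) and 3932 were unnamed here. No coordinates are given, since the array's build is not stated. Background was the 95th percentile of 2550 random control probes, a mean log2 level of 8.06 over arrays, and 64.1% of identifiers lay above it. Counts of arrays above background use the level of each array, which ran from 62.4 to 682 in deposited intensity. On slide 6, which held BALB/c controls only, 49.9% to 60.8% of identifiers lay above it, against 59.4% to 81.4% on BALB/c diet arrays. Such counts are therefore not at 1 common threshold. The number of arrays limits the precision.

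Before mice were treated as replicates, the 144 pairs of mice within a strain were compared over 23382 identifiers. A pair was counted as 1 sample where its differences on separate pairs of arrays correlated at 0.1 or less under both ways of pairing the arrays. This rule was set after 3 other measures of closeness had been looked at, none of which separated pairs cleanly, and before any fit with merged mice, but after the counts with every mouse counted singly had been seen. It took 2 pairs, CBA/Ca controls 3 and 8 and CBA/Ca diet mice 1 and 3, leaving 7, 6, 5 and 5 samples. The fit fixed before the data were examined counted every mouse singly, and its counts are given beside the main ones. CBA/Ca controls 1 and 2 were the next closest pair and stayed separate.

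All 4 groups entered 1 limma fit with an intensity trend in eBayes, with 19 residual degrees of freedom. Contrasts were the diet effect in each strain, their mean, their difference and the strain difference among controls. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 27 gene lists fixed before the data were examined (889 measured members) were tested with camera at its preset correlation of 0.01, and again with an estimated correlation and with fry. The estimated correlation ran from 0.0055 for choline and phospholipid to 0.831 for pancreas genes, with 0.589 for neutrophil and 0.505 for T cell genes. Where it lies far over 0.01, p-values at the preset are too small. The lists covered folate and methionine metabolism, choline and phospholipids, methylation machinery, imprinted genes, amino acid stress, p53, proliferation, interferon, inflammation, sterol and lipid synthesis, oxidative stress, immediate early and heat shock genes and circadian genes. They also covered erythroid, B, plasma, T, NK, neutrophil, red pulp macrophage, dendritic, megakaryocyte and stromal cells, and markers of kidney, pancreas, liver and adipose tissue. A further list of 28 squamous epithelium genes was written after those genes were seen. Spread between samples was the root mean square deviation from the group mean, compared by a two-sided exact permutation test.

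Named genes follow a rule fixed before the data were examined: per comparison and direction the 10 largest log2 fold changes among called, named genes above background in the higher group, up to 4 members of each list that passed, and 4 members of each of the 3 methyl-group lists. A gene that was not above background on any array of its lower group is given as a lower bound on its fold, the brighter mean against the background of each array. In data simulated from the real means and spread of all 42575 identifiers, 80.6% of genes planted at a log2 change of 1 were recovered for BALB/c and 74.6% for CBA/Ca. At a log2 change of 0.5 only 22.4% and 16.4% were recovered. The simulated noise was drawn independently for each gene and sample. Correlation between genes and shifts shared by samples of a slide were thus not covered, and recovery in the real data may differ. Alternatives covered background, normalization, probe summary, the deposited table, dim genes, samples in the fit, slide, single arrays, replicate numbers, the trend, the kidney tag and leaving out each mouse. The fit with each mouse counted singly, as the design was fixed, was also run. Alternatives added after the data were examined were CBA/Ca controls 1 and 2 also merged, each merged pair left out, the level of pancreas, adipose or squamous markers as a covariate, CBA/Ca controls 1, 2 and 5 left out (also with an estimated correlation for lists), BALB/c diet mice 6 and 8 left out, any 3 of the CBA/Ca control samples left out for the identifiers that fell, each list without each mouse, and only the BALB/c mice on slides with both groups.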

Results

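The spleens of 25 male mice of 2 inbred strains, BALB/c and CBA/Ca, were profiled to compare a diet short of methyl donors with a control diet. The differences within 2 pairs of CBA/Ca mice did not repeat between their arrays, and each pair was counted as 1 sample. The root mean square difference was 0.400 for diet mice 1 and 3, less than the noise between arrays (0.417), and 0.266 for controls 3 and 8, slightly above it (0.261). The groups then held 7 BALB/c controls, 6 BALB/c diet, 5 CBA/Ca control and 5 CBA/Ca diet samples. The 3 diet mice tagged as kidney showed 3 to 5 of 34 kidney markers above background, against 2 to 8 in the other mice. The strains shared no slide. Of the 10 slides, 3 held both BALB/c groups and 3 held both CBA/Ca groups.

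In BALB/c, 10 of 35 neutrophil genes rose on the diet (camera adjusted p = 2.20e-31; adjusted p = 0.0687 with an estimated correlation). Chil3, a chitinase-like protein of myeloid cells, rose by 2.15 ± 0.44 on the log2 scale (SE), and the collagenase Mmp8 by 2.06 ± 0.42. The granule protease Ctsg (1.82 ± 0.42), Ms4a3 (1.66 ± 0.38) and Mrgpra2b (1.60 ± 0.32) rose as well. The surface mucin Muc13 rose from 10.16 ± 0.51 (SD, n = 7) to 11.92 ± 0.32 (SD, n = 6), with a limma adjusted p of 3.61e-05, and stayed called in all 30 alternatives run. Chil3 kept its call in 18 of 30, Ctsg in 11 of 30, Ms4a3 in 11 of 29 and Mrgpra2b in 16 of 29. The T cell genes Cd4 (-0.58 ± 0.12), Cd5 (-0.80 ± 0.16) and Cd6 (-0.82 ± 0.16) fell, and the inhibitory receptor gene Pdcd1 fell from 9.90 ± 0.29 (SD, n = 7) to 8.90 ± 0.42 (SD, n = 6). Cd4, Cd5 and Cd6 kept their calls in 16, 18 and 21 of 30 alternatives, and Pdcd1 in 24 of 29.

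Other large rises in BALB/c were the glutamine synthetase gene Glul (1.97 ± 0.40), Prom1 (1.83 ± 0.39), Gdf3 (1.71 ± 0.38) and Dennd6a (1.69 ± 0.34). The falls included Tspan10 (-1.14 ± 0.22), Sostdc1 (-1.04 ± 0.19), the folate receptor family member Izumo1r (-1.02 ± 0.21) and Endou (-1.02 ± 0.16). The immunoglobulin variable genes Ighv1-47 (-1.12 ± 0.23), Ighv1-16 (-1.12 ± 0.23), Ighv5-12-4 (-1.01 ± 0.19) and Igkv4-73 (-0.99 ± 0.22) also fell. Each of these genes moved in its direction in 6 of 6 diet samples. Their calls held in between 12 of 29 alternatives (Gdf3) and 27 of 30 (Endou). Prom1 and Gdf3 were above background on 5 and 8 of 14 control arrays and Ighv1-47 on 6 of 12 diet arrays. In all, limma called 222 of 42575 identifiers, 132 up and 90 down, and 261 with each mouse counted singly. The count was 51 with the deposited value table, 25 with slide as a term (22 up, 3 down), 134 over the upper part of identifiers by mean level (62 up, 72 down), 73 without diet mice 6 and 8 and 6 over the mice on slides that held both groups, and it went from 74 without diet mouse 7 to 480 without diet mouse 2. None was called within single slides (limma, with 965, 4537 and 681 at an unadjusted p under 0.05).

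Of the 35 neutrophil genes in BALB/c, 25 did not pass, and 32 rose when adjusted over the list alone. Of 43 interferon response genes, 8 rose, 1 fell and 34 did not pass (14 up and 2 down adjusted over the list alone), including the antiviral genes Oas2 (1.06 ± 0.16), Ifit1 (0.91 ± 0.14) and Oasl2 (0.72 ± 0.12). The camera adjusted p was 3.56e-09 (adjusted p = 0.0687 with an estimated correlation). Of 29 p53 genes, 2 passed, the cell cycle inhibitor Cdkn1a, which rose (1.16 ± 0.17), and the receptor Eda2r, above background on 9 of 12 diet and 1 of 14 control arrays, with means of 8.01 and 6.70, and 4 passed adjusted over the list alone (camera adjusted p = 0.00448; adjusted p = 0.0687 with an estimated correlation). Of 33 T cell genes, 3 fell and 22 fell adjusted over the list alone (camera adjusted p = 9.71e-16; adjusted p = 0.150 with an estimated correlation). Of 23 plasma cell genes, 2 fell, Mzb1 (-0.61 ± 0.13) and Derl3 (-0.64 ± 0.14), with 7 adjusted over the list alone (adjusted p = 0.150 with an estimated correlation). Mzb1 kept its call in 14 of 30 alternatives and Derl3 in 13 of 30. The mean log2 change was above 0 for proliferation (0.34), inflammation (0.17), platelet (0.16), oxidative stress (0.12) and red pulp macrophage (0.11) genes and below 0 for liver (-0.65), dendritic (-0.24), B cell (-0.20) and stromal (-0.18) genes, which passed camera, with adjusted p from 0.0687 to 0.574 with an estimated correlation. Diet mice 6 and 8 had the lowest T cell (11.48 and 11.51) and B cell (13.18 and 13.10) list means in BALB/c and the highest erythroid (13.78 for each) and proliferation (13.18 and 13.11) means. Without both, the T cell shift was -0.22, and Cd4 (-0.41), Cd5 (-0.57) and Cd6 (-0.64) were not called (limma adjusted p from 0.108 to 0.140). The proliferation shift was then -0.04, and proliferation, oxidative stress, B cell, dendritic and stromal genes no longer passed camera (adjusted p from 0.0574 to 0.452). The proliferation mean was 0.18 without diet mouse 6 and 0.19 without diet mouse 8, and the platelet mean 0.25 without diet mouse 6. Within the 3 slides with both groups the mean shift was 1.00, 0.84 and 0.76 for neutrophil, -0.42, -0.11 and -0.35 for T cell, 0.17, 0.07 and 0.08 for p53 and 0.20, -0.40 and 0.33 for proliferation genes. In all, 14 lists passed camera and 0 with an estimated correlation, while fry called 7.

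In CBA/Ca, the serpin gene Serpina3b and several interferon response genes were higher in the diet samples, and a larger number of genes were lower. The serpin Serpina3b rose from 8.65 ± 0.17 (SD, n = 5) to 10.29 ± 0.24 (SD, n = 5), with a limma adjusted p of 0.000731. Slfn4 (1.23 ± 0.29), the chemokine receptor Ccr2 (0.97 ± 0.20), Oas2 (0.94 ± 0.19), Mx1 (0.93 ± 0.21), Muc13 (0.92 ± 0.22), Il18rap (0.92 ± 0.22), the beta-glucan receptor Clec7a (0.91 ± 0.15), the NK receptor Klrk1 (0.73 ± 0.17) and Ighv12-3 (1.44 ± 0.36) also rose, in 5 of 5 diet samples each. Il18rap was above background on 2 of 12 control arrays. Calls held in 29 of 31 alternatives for Serpina3b and 25 of 32 for Clec7a. For the other rises they held in 21 of 32 (Oas2) down to 9 of 32 (Ighv12-3), with 14 of 32 for Muc13.

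The largest falls in CBA/Ca were genes of keratinised squamous epithelium, which were far above background in controls 1, 2 and 5 and at background in all other mice. The list mean was 11.94, 11.98 and 11.36 in these controls, with 27, 27 and 26 of 28 members above background. Against the background of the arrays, Lor was at least 9.41-fold lower on the diet, Krt1 at least 7.96-fold, Krt4 at least 7.05-fold, Krt13 at least 6.37-fold, Sprr3 at least 6.36-fold and Krtdap at least 5.20-fold. Their SD among the controls was 3.84 to 4.29 on the log2 scale. The squamous list was written after these genes were seen.

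The CBA/Ca count was 464 identifiers, 82 up and 382 down, and depended on which mice were merged or left out. It was 890 with each mouse counted singly and 14 with controls 1 and 2 also merged. Without controls 1, 2 and 5 it was 3. Here and below, that setting left only control 4 and the merged controls 3 and 8. With the squamous level as a covariate it was 32, 26 up and 6 down. With slide as a term it was 1635, 417 up and 1218 down. That fit used single arrays, so the rise from 464 cannot be put down to slide alone. It was also 3, all up, without the 3 mice tagged as kidney, which left only diet mouse 4 and the merged diet mice 1 and 3. The count was 17 over the upper part of identifiers by mean level and 2 with only the CBA/Ca groups in the fit. It went from 16 without control 1 to 1061 without control 4. Within slides 8 and 10, limma called 2 and 0 (4627 and 3059 at an unadjusted p under 0.05).

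**Figure D1:**
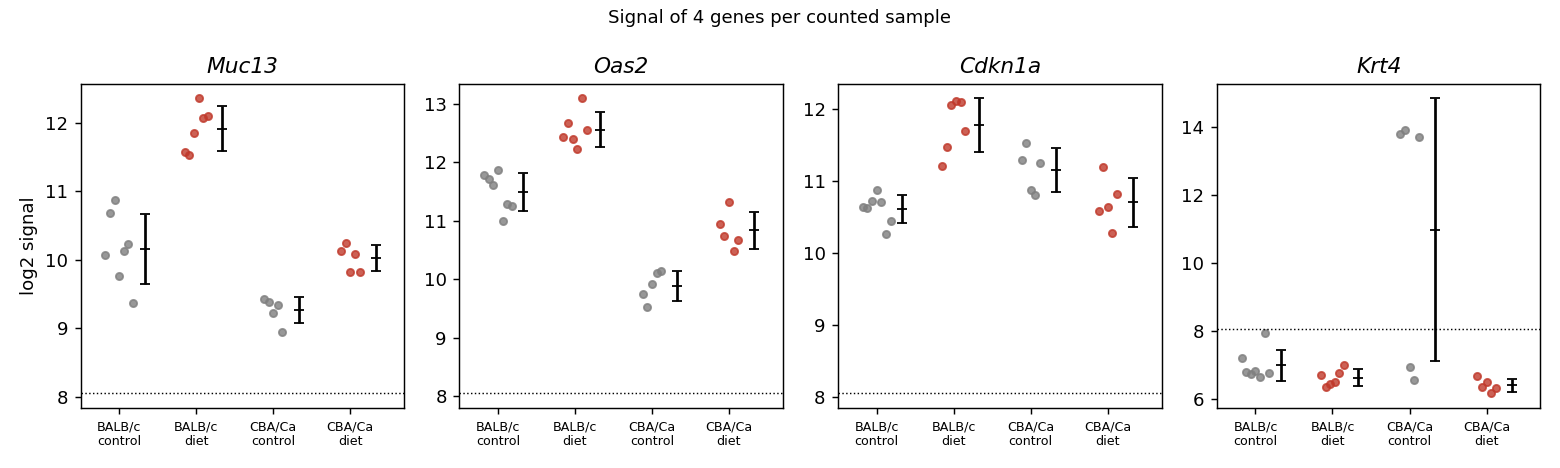
Log2 signal of Muc13, Oas2, Cdkn1a and Krt4 in each counted sample (points), with the group mean and SD beside them and the background level as a dotted line. Krt4 lay above background in 3 CBA/Ca controls.

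Fat-tissue genes were lower in CBA/Ca diet samples. Of 22 adipose markers, 6 fell and 16 did not pass (10 fell adjusted over the list alone), among them the lipogenic regulator Thrsp (-1.31 ± 0.23) and the adipokine gene Adipoq, which fell from 9.54 ± 0.19 (SD, n = 5) to 8.54 ± 0.13 (SD, n = 5). Thrsp was above background on 5 of 12 diet arrays. The camera adjusted p was 3.65e-15 (adjusted p = 0.000682 with an estimated correlation). Cidea was at least 1.46-fold lower. With the adipose level as a covariate no identifier was called in limma (0, with 1236 at an unadjusted p under 0.05). That level lay between 10.38 and 10.70 in the control mice and between 9.69 and 10.19 in the diet mice. Since these did not overlap, the covariate cannot tell the fat signal from the diet. Of 34 oxidative stress genes, 3 fell, among them Gsta4 (-1.11 ± 0.26) and Gpx2 (-2.24 ± 0.56), and 9 fell adjusted over the list alone, with adjusted p = 0.00675 with an estimated correlation. Of 36 sterol and lipid synthesis genes none passed in limma, and 5 fell adjusted over the list alone (adjusted p = 0.0230 with an estimated correlation). Fdps, a farnesyl diphosphate synthase, had a log2 change of -0.68 ± 0.18 (limma adjusted p = 0.0608 over all genes). Without controls 1, 2 and 5 the sterol list had a camera adjusted p of 0.247, and the oxidative stress list an adjusted p = 0.202 with an estimated correlation. Gpx2, above background on 7 of 12 control and 3 of 12 diet arrays, then had a log2 change of 0.05. Of 43 interferon genes 5 rose and 16 rose adjusted over the list alone, including Oas1a (0.74 ± 0.14). Their camera adjusted p was 4.46e-10 (adjusted p = 0.05001 with an estimated correlation). Without controls 1, 2 and 5 the mean shift of the interferon list was 0.19, against 0.30. Of 28 liver markers 1 fell, Apoc1 (-1.31 ± 0.29), and the heat shock gene Hspb1 fell (-2.10 ± 0.42).

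The mean log2 change in CBA/Ca was also below 0 for pancreas (-1.36), liver (-1.30), erythroid (-0.43), immediate early and heat shock (-0.40), folate and methionine (-0.36), proliferation (-0.27), stromal (-0.27), amino acid stress (-0.23) and imprinted (-0.18) genes. It was above 0 for platelet (0.25), NK (0.24), neutrophil (0.19) and dendritic (0.10) genes. Without control 4 the liver mean was -1.99, and without control 5 the proliferation mean was -0.42. The dendritic mean was 0.0624, 0.0633 and 0.0612 without control 1, control 2 and diet mouse 6. These lists passed camera, with adjusted p from 0.0612 to 0.603 with an estimated correlation. Without controls 1, 2 and 5 the means were -0.02 for neutrophil, -0.01 for dendritic and 0.08 for NK genes, and these, stromal and imprinted genes did not pass camera (adjusted p from 0.231 to 0.612). In all, 17 lists passed camera and 3 with an estimated correlation, while fry called 6.

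Among 41 folate and methionine cycle genes in CBA/Ca, 1 rose and 3 fell, and 12 fell adjusted over the list alone (adjusted p = 0.192 with an estimated correlation). Ahcyl2, related to the enzyme that splits S-adenosylhomocysteine, rose by 0.65 ± 0.15 and the glycine methyltransferase Gnmt fell (-1.23 ± 0.30). Bhmt2 and Nnmt also passed, with group means below background in both groups. Ahcyl2 kept its call in 13 of 32 alternatives and Gnmt in 11 of 31. Gnmt, Bhmt2 and Nnmt are also liver genes. The liver marker mean was 8.20 in control 4 and 11.41 to 12.32 in the other control mice. It was 8.21 to 10.22 in the diet mice, below all controls except control 4. The pancreas marker mean was 11.82 to 13.37 in the control and 10.07 to 12.15 in the diet mice, and adipose markers were lower on the diet as well. These values do not tell which tissue the signal of Gnmt, Bhmt2 and Nnmt came from. Without controls 1, 2 and 5, with fewer samples, Gnmt was at -1.34 and not called (limma adjusted p = 0.239). Its change was no smaller, so the lost call does not tie it to these controls. In BALB/c none of the 41 passed. Of 40 methylation machinery genes and 32 choline and phospholipid genes, none passed over all genes in either strain, and neither list passed camera, nor did the 20 circadian genes.

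Over both strains, Muc13 (1.32 ± 0.14), Slfn4 (1.18 ± 0.19), Oas2 (1.00 ± 0.12), Ifit1 (0.77 ± 0.11) and Oas1g (0.75 ± 0.11) rose. The neutrophil and myeloid genes Mmp8 (1.37 ± 0.32), Retnlg (1.19 ± 0.24), the lipoxygenase Alox5 (1.11 ± 0.21) and Cxcr2 (0.51 ± 0.10) rose too. The platelet genes F13a1 (0.78 ± 0.17) and F2rl2 (0.53 ± 0.11) and the red pulp macrophage regulator Spic (0.40 ± 0.09) rose. Spic kept its call in only 15 of 46 alternatives, and Gjb2 and Adipoq, given below, in 13 and 12 of 45, against 45 of 46 for Muc13 and for Oas2. Gjb2 (-1.36 ± 0.31) and Hspb1 (-1.25 ± 0.24) were called as lower, mostly through CBA/Ca. Gjb2 went from 8.70 to 8.42 in BALB/c and from 10.59 to 8.16 in CBA/Ca, and Hspb1 from 10.66 to 10.28 and from 13.07 to 10.95. Gjb2 was above background on 6 of 12 CBA/Ca diet arrays and Mmp8 on 7 of 12 CBA/Ca control arrays. Serpina3b, Prss8, Fxyd3, Igfbp6, Thrsp and Adipoq were also called, but in BALB/c they were above background on only 0, 5, 0, 8, 8 and 0 of 14 control arrays. Limma called 238 identifiers, 142 up and 96 down, and 6 without CBA/Ca controls 1, 2 and 5. More fell than rose with each mouse counted singly (232 up, 261 down of 493), with slide as a term (247 up, 402 down), with the deposited value table (96 up, 137 down) and without CBA/Ca control 4 (219 up, 775 down). Leaving out the merged CBA/Ca controls 3 and 8 also gave more falls (157 up, 422 down). Of 43 interferon genes 13 rose and 30 did not pass (19 up and 1 down adjusted over the list alone; adjusted p = 0.0123 with an estimated correlation, and 0.0813 without CBA/Ca controls 1, 2 and 5). Of 22 adipose markers 4 fell (12 adjusted over the list alone; adjusted p = 0.00312 with an estimated correlation), while 0 of the 22 passed in BALB/c. Of 35 neutrophil genes 7 rose (24 adjusted over the list alone; adjusted p = 0.0897 with an estimated correlation), while 0 of the 35 passed in CBA/Ca. Of 34 kidney markers, 4 of them above background, 1 fell (camera adjusted p = 0.0328; adjusted p = 0.146 with an estimated correlation).

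**Figure D2:**
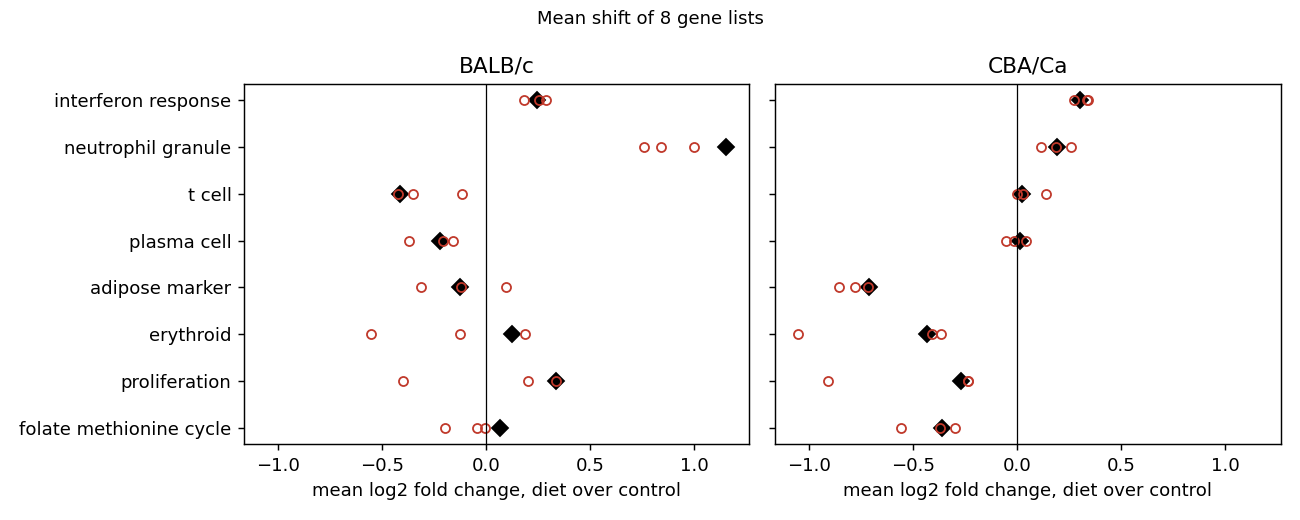
Mean log2 fold change of 8 gene lists, diet over control, in each strain over all samples (diamonds) and within each slide that held both groups (circles). The interferon list lay above 0 on all 6 slides.

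The diet effect differed between strains for 34 identifiers, 22 more positive and 12 more negative in CBA/Ca, for 112 with each mouse counted singly and for 11 without BALB/c diet mice 6 and 8. Cdkn1a had a difference of -1.61 ± 0.25 (limma adjusted p = 0.0120), Klf5 of -2.23 ± 0.41, Fabp5 of -1.79 ± 0.34 and Pafah2 of -1.44 ± 0.28. The immunoglobulin genes Igkv3-2 (1.06 ± 0.15) and Ighv1-16 (1.88 ± 0.35) went the other way. None of the 34 was called without CBA/Ca controls 1, 2 and 5 (limma, 0 identifiers, with 4399 at an unadjusted p under 0.05). The differences were then -1.29 for Cdkn1a, -1.70 for Klf5, -0.92 for Fabp5, -1.36 for Pafah2, 1.04 for Igkv3-2 and 1.37 for Ighv1-16. Slide as a term gave 13 more positive and 50 more negative, the deposited values gave 0 and 4, and leaving out CBA/Ca control 4 gave 119 and 499. Leaving out the merged CBA/Ca controls 3 and 8 gave 96 and 257. Fold changes of the strains correlated at 0.01 across identifiers, which are not independent replicates. The strains shared 5 identifiers called up and 2 called down, against 0.254 and 0.808 for independent lists, and 1 was called in opposite directions. Serpina3b, among the 5, was above background on 0 of 14 control and 5 of 12 diet arrays in BALB/c.

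Among controls, CBA/Ca differed from BALB/c at 9754 identifiers, 4565 higher and 5189 lower, and at 11280 with each mouse counted singly. Ighg1 was at least 15.6-fold higher in CBA/Ca and Ighv5-16 at least 20.2-fold. Hormad1 was at least 13.7-fold lower, Cd300c2 at least 7.27-fold and Serpina3a at least 3.18-fold. C1s1 (-4.49 ± 0.15), Slfn8 (-4.31 ± 0.22) and H2-Q8 (-3.75 ± 0.21) were lower. The pancreas genes Cpa1 (5.23 ± 1.36) and Clps (5.58 ± 1.35) were higher in CBA/Ca, and were above background on 5 and 4 of 14 BALB/c control arrays. Slfn8 was above background on 7 of 12 CBA/Ca control arrays. Strain and slide cannot be told apart, and sequence variants under probes lower a signal. Median scaling gave 3914 higher and 10389 lower, and the deposited values gave 11853 higher and 1683 lower. These scalings moved the median of all identifiers by -0.15 and 0.29.

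Spread between samples did not differ detectably. Root mean square deviation was 0.360 ± 0.034 (SD, n = 6) on the diet and 0.328 ± 0.061 (SD, n = 7) in controls in BALB/c (exact permutation p = 0.269). It was 0.340 ± 0.124 (SD, n = 5) and 0.335 ± 0.061 (SD, n = 5) in CBA/Ca (exact permutation p = 0.968).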

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

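The tests of squamous epithelium and of merged controls for the CBA/Ca falls, and those without other sets of 3 controls or without BALB/c diet mice 6 and 8, were chosen after the result was seen. Of 226 groups of samples examined, 17 held a sample far from the others. The cutoff is set to flag about 1 in 20 by chance, and the groups share samples, so no excess is read from this. CBA/Ca diet mouse 6 lay apart in Hspb1 (9.16 and 8.98 for separate identifiers), Igfbp6 (8.60), F13a1 (11.43), Clec7a (11.25), Sprr3 (6.81) and in its root mean square deviation (0.556, against 0.263 to 0.335 in the other diet samples). Other such values were Dennd6a in BALB/c diet 5 (9.29), Cd6 (13.16) and H2-Q8 (13.46) in BALB/c control 10, Nnmt in CBA/Ca diet 5 (7.09), Gjb2 in CBA/Ca control 4 (7.95), Adipoq in BALB/c control 6 (7.20), Ces1d in BALB/c diet 8 (8.36), Pafah2 (9.31) and Slfn8 (7.07) in CBA/Ca control 1, and Igkv3-2 in the merged CBA/Ca diet 1 and 3 (13.05). The values given for Sprr3, Nnmt, Gjb2, Adipoq and Slfn8 lay below background (8.06).

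The diet effect differed between strains at 34 identifiers by limma's test of the difference (CBA/Ca minus BALB/c, log2). These included Cdkn1a (-1.61), Klf5 (-2.23), Ces1d (-2.07), Fabp5 (-1.79), Pafah2 (-1.44), Igkv3-2 (1.06) and Ighv1-16 (1.88). The BALB/c means of Ces1d, 7.37 in controls and 7.74 on the diet, were below background. Of 100 splits, 1 gave as many identifiers, the real one, and the highest other gave 1.

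More identifiers fell than rose in CBA/Ca (382 and 82), but not in every setting. With the squamous level as a covariate 6 fell and 26 rose. Without the kidney-tagged mice 0 fell and 3 rose (limma, 4199 at an unadjusted p under 0.05). Only diet mouse 4 and the merged diet mice 1 and 3 were then left, too few to judge the balance. Without controls 1, 2 and 5 the median log2 fold change of the 382 that fell went from -1.38 to -0.46. Squamous epithelium carried into these samples, as a source of part of the falls, would give such a change. Of the 382, 353 stayed below 0 and 174 stayed at -0.5 or lower. The 382 were called with these controls in the fit, so some shrinkage could follow from that choice alone. Without any other 3 of the 5 control samples the median was between -1.96 and -1.03, and limma called 2 to 1077 identifiers. A low count was thus not particular to leaving out controls 1, 2 and 5 (3 called). A diet effect on part of the falls stays open. Merging controls 1 and 2 left 14 calls, against 29 to 945 for the 9 other pairs. The pairs with 29 were control 5 with control 1 or 2, so the loss may follow the squamous signal as much as the likeness of controls 1 and 2.

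Neutrophil genes were higher and T cell genes lower on average in BALB/c (mean shifts 1.16 and -0.41; adjusted p = 0.0687 and 0.150 with an estimated correlation). On the 3 slides with both groups the median mean shift of the neutrophil list was 0.84. For these genes this argues against single-group slides as the whole cause, although these slides shared mice. Diet mouse 5 had the highest neutrophil list mean in BALB/c and was on slides 2 and 3, with shifts of 1.00 and 0.84. Slides 2 and 3 were not tested without it, so they do not show the shift apart from this mouse. On slide 4, which did not hold it, the shift was 0.76. With 1 mouse left out the lowest shift was 0.88 (SE 0.31), without diet mouse 5, which does not settle how much of it 1 mouse could carry. Without diet mice 6 and 8, which had the highest erythroid and proliferation levels, the neutrophil shift was 1.22 and the T cell shift -0.22. A change in cell makeup and a change per cell were not told apart by a test here.

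Interferon genes were higher on average in both strains. Their mean shift was above 0 on 6 of 6 slides that held both groups, which argues against differences between slides as the whole cause, although these slides shared mice. Without CBA/Ca controls 1, 2 and 5 the mean shift in CBA/Ca was 0.19 (SE 0.0824; adjusted p = 0.481 with an estimated correlation), against 0.30, so the squamous signal stays open as a source of it there. A diet effect stays open as well.

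Counting the real split, as many identifiers were called in 2 of 100 splits of the samples for BALB/c (222, highest other 533), 3 of 100 for CBA/Ca (464, highest other 525), 1 of 100 over both strains (238, highest other 3) and 1 of 100 for the strains (9754, highest other 3354). The CBA/Ca splits with more calls exchanged control 4 with 1 diet mouse and kept controls 1, 2 and 5 together. For lists, again counting the real split, 8 of 100 splits gave as many in BALB/c (14, highest other 15), so chance cannot be excluded there, 2 of 100 in CBA/Ca (17, highest other 18) and 2 of 100 over both strains (19, highest other 20).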

How the results depend on the processing

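Counting each mouse singly was the fit fixed before the data were examined, and the merged pairs were chosen after its counts had been seen. The settings that merge CBA/Ca controls 1 and 2, leave out merged pairs, CBA/Ca controls 1, 2 and 5 or BALB/c diet mice 6 and 8, use a tissue level as a covariate or keep only BALB/c slides with both groups were chosen after the data were seen. Counts are of identifiers in limma in the order BALB/c, CBA/Ca, both strains, their difference and the strains (222, 464, 238, 34 and 9754), and causes were not tested unless the setting itself tests fewer genes or samples. The deposited table gave 51 for BALB/c and 4 for the difference, and the mean of probes 19 for the difference. The upper part by level gave 134, 17, 106 and, for the strains, 5409, with fewer genes tested. Only the compared groups gave 50 and 2. Slide as a term, fitted on single arrays, gave 25, 1635, 649 and 63. First arrays gave 195 in CBA/Ca, 106 over both and 2 for the difference, and second arrays 59, 242, 88 and 0 (5151 at an unadjusted p under 0.05). Without the kidney-tagged mice CBA/Ca had 3, both strains 9 and the difference 0 (5997 unadjusted). Each mouse counted singly gave 890, 493 and 112 for CBA/Ca, both and the difference, and merging controls 1 and 2 gave 14, 117 and 9. Leaving out merged controls 3 and 8 gave 713, 579 (157 up, 422 down) and 353 (96 more positive, 257 more negative), and leaving out merged diet mice 1 and 3 gave 37, 156 and 7. The pancreas level gave 182 in CBA/Ca, 14 for the difference and 4946 for the strains. The adipose level gave 108 in BALB/c, 0 in CBA/Ca (1236 unadjusted), 0 over both (1653), 0 for the difference (2147) and 22 for the strains. It did not overlap between CBA/Ca control and diet mice, or between BALB/c (8.70 to 9.30) and CBA/Ca (10.38 to 10.70) controls. This setting therefore cannot tell adipose level from diet in CBA/Ca or from strain. The squamous level gave 32, 18, 1 and 6343 from CBA/Ca on. Without CBA/Ca controls 1, 2 and 5 these were 3, 6, 0 (4399 unadjusted) and 5587. Without BALB/c diet mice 6 and 8 BALB/c had 73 and the difference 11. BALB/c slides with both groups gave 6 in BALB/c, 43 over both and 0 for the difference (3683 unadjusted).

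Of 10 same-numbered pairs of mice, 4 correlated over 0.1 (range -0.15 to 0.29) and 3 correlated best with their own number, so the numbers were not taken to pair mice. The replicate block gave 5, 1774 (1034 up, 740 down), 145 and 0 (7644 unadjusted). Leaving out 1 mouse gave 74 to 480 for BALB/c, 16 to 1061 for CBA/Ca, 105 to 994 over both, 6 to 618 for the difference and 7981 to 9769 for the strains. BALB/c fell to 74 and 77 without diet mice 7 and 8, to 79, 95 and 117 without controls 10, 9 and 6, and was 346 and 480 without diet mice 1 and 2. CBA/Ca was 16, 22 and 35 without controls 1, 2 and 5, 1061 without control 4, and 140, 72, 95 and 265 without diet mice 4, 5, 6 and 8. Lists passing were 0, 3 and 2 with an estimated correlation and 7, 6 and 8 with fry, against 14, 17 and 19. In CBA/Ca they were 11 with the adipose level, 11 with the squamous level and 11 without controls 1, 2 and 5, and over both strains 9 with the adipose level. With an estimated correlation, singly counted mice gave 0, 3 and 2 lists, and leaving out CBA/Ca controls 1, 2 and 5 gave 1 in CBA/Ca and 1 over both strains. Without BALB/c diet mice 6 and 8 they were 0 in BALB/c and 2 over both strains. The CBA/Ca spread difference (0.00503) was -0.00175 without background correction, -0.0388 with the deposited table and -0.0656 without the kidney-tagged mice, and -0.0760 to 0.0353 leaving out 1 mouse. That of BALB/c was 0.0161 to 0.0491. Signs turned for Cpa1 (-0.11) and Pnliprp1 (-0.10) between strains with the pancreas level, for Krt1 (0.00426), Sprr3 (0.16) and Gpx2 (0.12) in CBA/Ca with the squamous level, and for Sprr3 (0.0631) and Gpx2 (0.0473) without controls 1, 2 and 5. Among genes not called, signs turned for Ccna2 (-0.0151, slide as a term) and Mcm6 (-0.00767, slides with both groups) in BALB/c, and for Ddit4 (0.0344, without the kidney-tagged mice) and H19 (0.0394 with the squamous level, 0.0130 without controls 1, 2 and 5) in CBA/Ca. Over both they turned for Bpgm (0.0232, adipose level), Gpx2 (0.0337), Gsta2 (0.0216) and H19 (0.0579) with the squamous level, and H19 (0.0368) without controls 1, 2 and 5. Over the named genes and settings, 2226 of 2620 values in BALB/c, 2322 of 3034 in CBA/Ca, 4249 of 4830 over both, 387 of 868 for the difference and 563 of 592 for the strains kept direction and side of the threshold. For the strains more were higher than lower with the mean of probes (5061 and 4899) and the pancreas level (2496 and 2450). Signal over background limits dim genes.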

Other observations

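The list comparisons were in the design, but the merged pairs and the tests without CBA/Ca controls 1, 2 and 5 were chosen after results had been seen. The diet effect on gene lists differed between strains for 17 lists by camera, of which oxidative stress (-0.56, CBA/Ca minus BALB/c; adjusted p = 0.0130 with an estimated correlation) and adipose genes (-0.59; adjusted p = 0.0263 with an estimated correlation) also passed with an estimated correlation. Neutrophil genes differed by -0.96 and T cell genes by 0.44 (adjusted p = 0.307 for each with an estimated correlation). Without CBA/Ca controls 1, 2 and 5 the differences were -0.37 for oxidative stress and -0.50 for adipose genes (adjusted p = 0.141 for each with an estimated correlation). In CBA/Ca the oxidative stress list had a mean of -0.44 and a median of -0.16, and without these controls Gsta2 was at -0.11, against -2.09.

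Pancreas markers had a list mean of 13.03, 10.96, 10.51 and 13.01 in BALB/c controls 2 and 7 and diet mice 1 and 8, and between 7.02 and 7.97 in the other BALB/c mice. In CBA/Ca the list mean ran from 11.82 to 13.37 in controls and from 10.07 to 12.15 in diet mice. Liver markers were at 8.20 in CBA/Ca control 4, from 11.41 to 12.32 in the other CBA/Ca controls and from 8.21 to 10.22 in CBA/Ca diet mice.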
